A study of Oryza sativa with 3 samples.

How the data were processed

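Leaf RNA of 3 replicates of rice cultivar Kitaake was measured, 1 array each. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase on a column, cleaned on a QIAGEN column, labelled with biotin with an Affymetrix express labelling kit and hybridised to an Affymetrix rice array. The deposited values are log2 signals per probe set, and the submitters' processing notes name RMA as the only tool. Its version, background settings and annotation are not given in the sources used here. As usually run, RMA corrects the background, sets the arrays to 1 common distribution by quantile normalization and summarises each probe set by median polish. The deposited columns had equal medians of 5.63 (log2) and a range from 2.56 to 14.78, so the log2 scale and the between-array normalization could be seen in the values, while nothing shows whether arrays of another series were normalised with them. Their SDs were 2.44, 2.45 and 2.39, so the distributions were alike but not identical. Scanner files and detection calls were not used here.

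Median polish over few arrays returns exact ties. Here 24.2% of probe sets (13841) had the same value on all 3 arrays, and 47.7% were equal between replicates 1 and 2, within a tolerance of 1e-09. Simulated noise passed through median polish gave 43.6% of probe sets equal on all 3 arrays. An SD of 0 therefore does not mean an exact measurement. Values equal on all 3 arrays made up 39.1% of the lowest decile of mean signal and 6.4% of the highest. SDs over arrays may therefore understate the error of dim probe sets, which was not measured. Quantile normalization, where it was applied, fixes the overall distribution, so a shift of most genes in 1 replicate could not be seen.

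Of 57381 probe sets, 187 controls and reporters were set aside and 57194 were analysed. The platform's gene annotation named 1 gene symbol for 22436 of them; 95 probe sets had several symbols and 34663 had none here. The 17905 genes were matched by gene identifier to a RefSeq table of assembly ASM3414082v1, used only for names; all were found and 2459 had a published name. No coordinates are given, since no build is named for the arrays. A gene with several probe sets (3444 genes) took the value of the probe set whose suffix is neither _x_at nor _s_at, and among those the one with the highest mean.

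Gene lists, tests and the rule for named genes were fixed before the data were examined, with 1 departure. The lists had been written as RAP loci and as words of product descriptions, and the annotation held only symbols and synonyms. The 27 lists were therefore rewritten as patterns of published names, from the names alone, before any gene's values had been looked at, though after array-wide summaries and control probe sets had been seen. Some members were added (WRKY71, SGT1, Ehd3, Ehd4, MADS56 and others) and the lists cover only genes with a published name. Named genes are every matched member of the lists first written by locus and, of each other list, the 2 with the largest SD and the 2 with the highest mean signal. The rule's last part, the 10 named genes with the largest SD among those past the excess-spread test, took none. Genes outside the rule are said to be so where they appear. MADS15 belongs to the flowering list; the remark that its SD was the largest of all named genes was made after the values were seen, as was the look at its probe sets.

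Agreement between arrays was described by the SD of the log2 difference over probe sets, Pearson's r and the count of probe sets at least 2-fold apart. Excess spread was tested with limma 3.58.1 in R 4.3.3: a model with an intercept, eBayes with trend and robust settings, and a one-sided F test of the residual variance against the trended prior, with Benjamini-Hochberg adjustment at 0.05. Each list was set against 10000 random lists of the same size, drawn within 20 bins of mean signal for the spread and the shifts, and without bins for the signal. A shift is the median over members of 1 array minus the mean of the other arrays. A value below the 2.5th or above the 97.5th percentile was called outside. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

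The variance test was tested on simulated data with the real mean signals of 57194 probe sets, 200 of which had added spread. With normal noise it called 41 of 74 at an added SD of 0.5, 51 of 68 at 1 and 57 of 58 at 2, with 6 false calls. With the same spread passed through median polish it called 0 at each size. The list percentiles were tested on 17905 simulated genes with normal noise of the same SD for every gene, independent between genes. It held no median polish and no ties, so these rates may not hold for the deposited values. Of 40 lists of 15 genes shifted by 0.2 on replicate 2, 35 lay outside, as did 10 of 40 shifted by 0.1 and 0 of 60 without a shift. Alternatives were quantile normalization again, centring each array on its median, dropping probe sets below the median signal or with shared-probe suffixes, averaging probe sets of a gene, other eBayes settings, a 1.5-fold threshold, means in place of medians, and leaving out each replicate in turn. Leaving out a replicate kept the deposited values of the other arrays, without a new RMA fit. Without replicate 3 a list median of 0 can fall on values tied between replicates 1 and 2, and does not show that these were alike. No group comparison was made, because the labels give 1 group.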

Results

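The data describe messenger RNA in leaves of Kitaake, a fast-cycling japonica cultivar of rice, taken from plants grown for 6 weeks in a greenhouse. There was 1 group of 3 replicates, grown at the same time, and each replicate was hybridised to 1 Affymetrix rice array. The design holds no treatment, genotype or time contrast, so the questions it can answer are which genes give signal in these leaves and how far the replicates differ. Nothing in the labels says how many plants a replicate pooled, so the spread between replicates may be partly technical. The number of arrays, 3, limits the precision of every value. Values are log2 signals, given as mean ± SD over n = 3 arrays. The arrays shared a median of 5.63 over all probe sets, and their 75th percentiles were 7.91, 7.93 and 7.80 for replicates 1, 2 and 3. A signal depends on its probes as well as on the transcript, so no gene is ranked against another gene. List percentiles of signal carry the same limit: they place probe sets among probe sets, describe signal and not amounts of transcript, and were planned without a test.

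The first question was which groups of genes gave signal in the leaf. The 4 lists of photosynthesis had median signals above those of the random lists drawn, as signal of the probe sets only. The 3 light-harvesting genes had a median signal of 14.16, above that of every one of 10000 random lists of the same size, with LHCP (LOC4333359), a chlorophyll-binding antenna protein, at 14.50 ± 0.01. The 8 genes of photosystems and electron transport had a median of 14.13, among them PETE (plastocyanin, LOC4339833) at 14.66 ± 0.00 and OEE3 (LOC4343515), a protein of the oxygen-evolving complex, at 14.32 ± 0.08. The highest value on any array was 14.78, near these signals, and whether the scale compresses differences there was not tested. The 11 genes matched by name to the Calvin cycle and photorespiration had a median of 12.04, and 10 of them were above background. The median is the value of CFBP1. CFBP1 and GLDH1, outside the rule for named genes, entered by name alone, and their place in these pathways was not checked. RBCS1, named after its value was seen, was at 3.44 ± 0.10. Rubisco activase RCAA1 (LOC4351224) was at 14.19 ± 0.07 and glycolate oxidase GLO1 at 13.38 ± 0.00 (11.02 as a mean of its probe sets). The 16 genes of chlorophyll synthesis had a median of 11.60, with protochlorophyllide reductase PORB at 13.29 ± 0.04 and geranylgeranyl reductase CHLP at 13.16 ± 0.02.

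The clock and flowering-time lists also had median signals above most random lists. All 7 measured circadian clock genes lay above background, with a list median of 11.90 at the 99.98th percentile of random lists. GI (LOC4325329), the GIGANTEA gene that links the clock to day length, had a signal of 13.34 ± 0.00. The pseudo-response regulators PRR95 and PRR73 had 13.70 ± 0.02 and 13.02 ± 0.00, and the morning-phased LHY had 11.71 ± 0.14. The 12 flowering-time genes had a median of 9.72 at the 97.66th percentile, and 11 of them were above background on every array. Hd3a (LOC4340185), the rice florigen, which is made in leaves and moves to the shoot tip, had a signal of 11.22 ± 0.23. The florigen-responsive MADS14 (LOC4334140) had 11.96 ± 0.24 and MADS18 had 12.17 ± 0.15. As means of their probe sets PRR73, LHY and MADS14 had 11.65, 8.04 and 10.63. Hd1 (LOC4340746), which promotes flowering in short days and delays it in long days, had 6.94 ± 0.00. The 23 genes matched by name as cytosolic ribosome, with a median of 12.30, and the 6 reference genes, with 11.81, completed the 8 lists above the 97.5th percentile. ACT1, the actin gene often used as a reference, was at 11.87 ± 0.00 and REFA1, an elongation factor, at 13.74 ± 0.03.

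Markers of other tissues differed in signal by list. None of the 9 anther and tapetum genes was above background on every array, and their median was 4.38. Of the 7 shoot meristem genes 2 were above background: FON1, a meristem receptor kinase, at 8.84 ± 0.25 and OsWOX4 at 6.10 ± 0.08. The meristem homeobox gene OSH1 (LOC4333973) had a signal of 3.25 ± 0.10. The 49 genes of cyclins and mitosis had a median of 5.19, lower than every random list, with 21 above background. The 10 seed storage genes had a median of 5.30 at the 1.36th percentile, and 5 of them were above background, among them GLB and GLUA-2 at 9.96 ± 0.17 and 9.47 ± 0.13 (GLUA-2 at 7.94 as a mean of its probe sets). Of the 5 root genes, with a median of 6.15, 3 were above background, among them the silicon channel Lsi1 at 9.10 ± 0.15 and the iron transporter IRT1 at 7.96 ± 0.47, while Lsi2 had 4.30 ± 0.19. Cell wall growth genes (58, median 5.93) and diterpenoid phytoalexin genes (15, median 5.91) completed the 6 lists below the 2.5th percentile. Background here is the 95th percentile of the array's 64 reporter probe sets, a bound chosen after the data were seen, at 5.64, 5.60 and 5.77. By it 13299 of 17905 genes (74.3%) were above background on all 3 arrays.

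**Figure D1:**
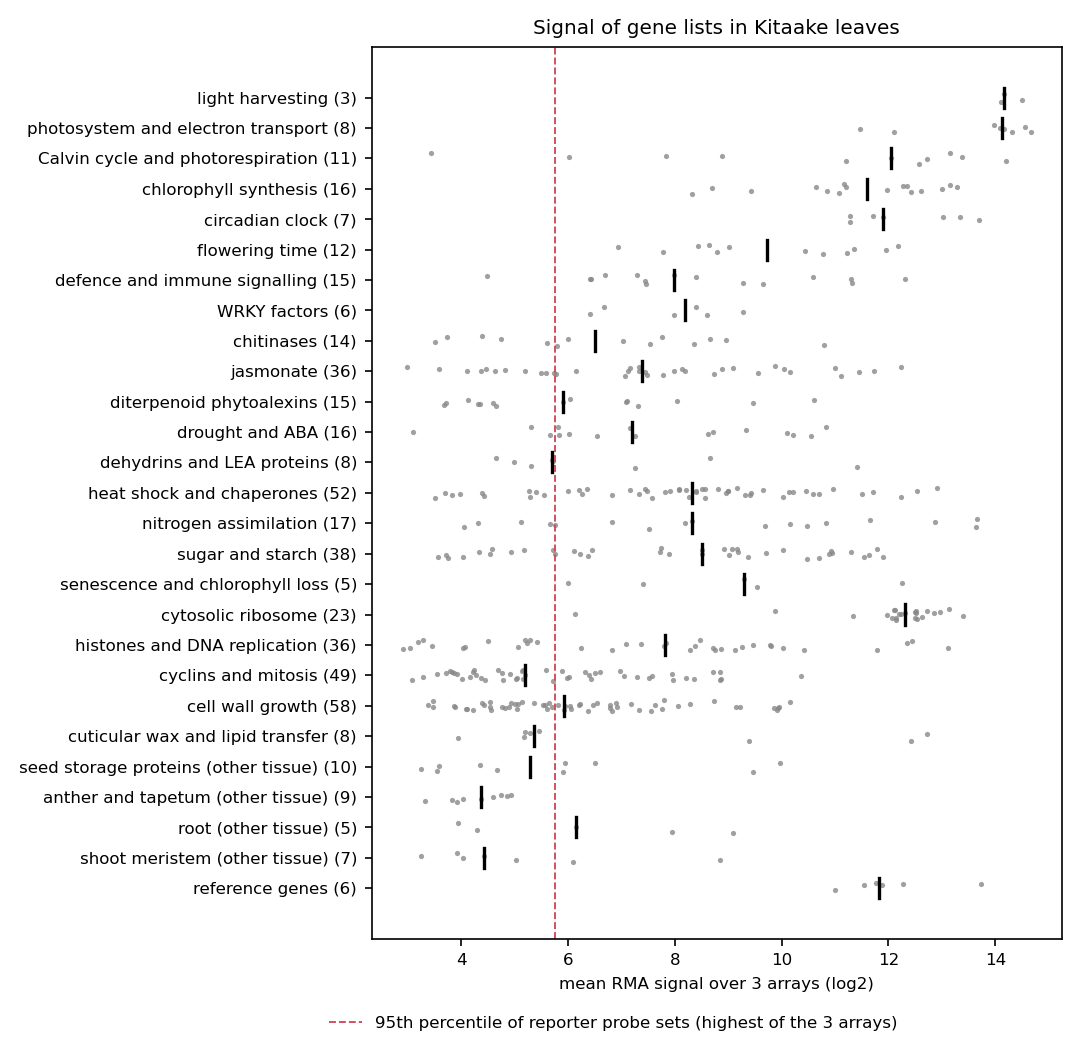
Mean signal over the 3 arrays (log2, horizontal axis) of each member of the 27 gene lists, with the list size in brackets. Each point is a gene, the black bar is the list median and the dashed line is the highest of the 3 reporter bounds, 5.77. Photosynthesis lists centre on 11.60 to 14.16 and the anther and tapetum list on 4.38.

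The remaining lists lay inside the central 95% of random lists for signal. They held genes well above background nonetheless. In nitrogen assimilation, median 8.32 over 17 genes, plastid glutamine synthetase GLN2 had 13.66 ± 0.06 and Fd-GOGAT, its partner enzyme, had 13.63 ± 0.08. In sugar and starch metabolism, median 8.51 over 38 genes, AGPS2 had 11.89 ± 0.04 and the sucrose transporter OsSUT2 had 11.79 ± 0.04. The list of senescence and chlorophyll loss, median 9.30 over 5 genes, included NYC1 at 12.26 ± 0.03 and the stay-green gene SGR at 7.41 ± 0.35. The jasmonate list had a median of 7.39 over 36 genes, with the repressors JAZ1 and JAZ7 at 12.24 ± 0.03 and 11.72 ± 0.01. Histones and DNA replication (36 genes) had a median of 7.81, with H2B.5 at 13.12 ± 0.01. The wax and lipid transfer list (8 genes) had 5.37, with LTP at 12.72 ± 0.24, and the list of dehydrins and LEA proteins (8 genes) had 5.71, with LIP9 at 11.41 ± 0.05. As means of their probe sets GLN2, Fd-GOGAT, OsSUT2, SGR and LIP9 had 11.52, 11.25, 9.06, 8.57 and 7.03. Chitinases (14 genes) had 6.51, defence and immune signalling (15 genes) 7.99, WRKY factors (6 genes) 8.20, drought and ABA (16 genes) 7.21, and heat shock and chaperones (52 genes) 8.33.

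The second question was how far the replicates differed. MADS15 (LOC4342214), an APETALA1-like gene that florigen induces, had the largest SD of all named genes. Its signal was 5.57 in replicate 1 against 9.12 in replicate 2 and 8.67 in replicate 3. The value in replicate 1 lay below the background bound of 5.64, so no fold is given. Of its 4 probe sets 3 were lower in replicate 1 by at least 2.42, of which 1 was above background there, and the other was below background on every array. Across all 57194 probe sets the median SD was 0.07, and 556 (0.972%) spanned at least 2-fold. The median SD was 0.06 without replicate 1 or 2 and 0.01 without replicate 3, where 27254 probe sets were equal on both arrays. Replicates 1 and 2 differed with an SD of 0.15 over probe sets (Pearson r = 0.998), and replicate 3 differed from them with SDs of 0.25 and 0.25 (r = 0.995 for both); r is across probe sets, which are not independent replicates. Probe sets at least 2-fold apart numbered 182 between replicates 1 and 2, 325 between 1 and 3, and 293 between 2 and 3.

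No probe set passed the limma variance test for excess spread at an adjusted p of 0.05 over all probe sets, nor did any list member when adjusted over the list alone, and 4943 had an unadjusted p under 0.05. The test made no calls in simulated values of this kind either: in median-polished data it found 0 of 58 probe sets with an added SD of 2, against 57 of 58 under plain normal noise. With 0 calls the Fisher tests of lists among called genes were void, and differences between replicates below are values of these arrays and not tested changes.

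Of the 27 gene lists, 5 spread more between replicates than the central 95% of random lists matched on signal. The 6 WRKY factors had a median SD of 0.27 against 0.11 for matched lists (99.64th percentile), and WRKY76 (LOC4347069), a repressor within the defence response, ranged over 3.61-fold. Cell wall growth genes had 0.15 against 0.08 (99.87th percentile), led by the expansins EXPB3 (9.95 ± 0.99) and EXPA2 (7.79 ± 0.89). Heat shock genes had 0.13 against 0.09 (99.01th percentile), flowering-time genes 0.15 against 0.09 (98.56th) and drought and ABA genes 0.15 against 0.08 (97.95th). Without replicate 2 the spread calls ended for flowering-time (0.08, 52.77th percentile), WRKY (95.43th), heat shock (87.99th) and drought lists (87.96th). They also ended for flowering-time (94.56th) and WRKY lists (93.19th) with replicates 1 and 2 averaged, an alternative chosen after seeing the data. The drought call ended among probe sets above the median signal (96.18th), and the heat shock call with quantile normalization again (97.01th) and without replicate 3 (93.69th). In the drought list LEA3 (LOC4339480), a desiccation protein, was at 6.47 in replicate 3 against 4.98 and 4.49, both below background. ABA8OX1, an enzyme of abscisic acid breakdown, was at 9.21 in replicate 2 against 8.82 and 8.11. Without replicate 3 the cell wall and drought spreads were 0.04 and 0.09, still outside. Chance would put 1.35 lists outside the central 95% if genes varied independently, which genes of a list need not do. The other 22 lists, defence among them (97.35th percentile), lay inside.

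The defence list was higher in replicate 2. Of the 15 genes of defence and immune signalling, 13 were higher in replicate 2 than the mean of the other replicates and 0 were lower, with a median difference of 0.20 (99.98th percentile of matched lists). WRKY76 was at 8.89 against 7.04 and 8.04 in replicates 1 and 3. The pathogenesis-related gene PBZ1 (LOC4352491) was at 12.81 against 11.74 and 12.39, WRKY62 (LOC4347070) at 6.78 against 6.23 and 6.21, and the kinase OsMPK3 at 6.98 against 6.55 and 6.57. All 6 WRKY factors were higher in replicate 2 than the mean of the other replicates, with a median difference of 0.37 (99.99th percentile). WRKY9 and WRKY51 were nonetheless highest in replicate 1, at 9.41 and 8.77 against 9.34 and 8.76 in replicate 2. Of the 6, 3 (WRKY62, WRKY71 and WRKY76) also belong to the defence list. The chitin receptor gene RLK10 (CERK1) was at 7.55 in replicate 2 against 7.26 and 7.05, and CEBIP at 6.48 against 6.38 and 6.44. Other defence genes peaked elsewhere. NH1 and XB15 were highest in replicate 1, at 7.62 and 9.40 against 7.61 and 9.31 in replicate 2. RBOHB was highest in replicate 3, at 11.41 against 11.34 in replicate 2. Over alternatives that kept the call the defence median in replicate 2 ran from 0.14 to 0.31.

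The list of diterpenoid phytoalexin genes, for antimicrobial compounds of rice, was likewise higher in replicate 2 and lower in replicate 1. Of its 15 genes, 7 of them above background, 10 were higher and 4 lower in replicate 2, with a median difference of 0.18, above every matched list. In replicate 1 the median was -0.12 (0.06th percentile), with 13 lower and 1 higher. CYP71Z7 was at 6.50, 7.72 and 7.08 in replicates 1, 2 and 3, and KSL5 at 6.69, 7.79 and 7.46. CYP71Z6 was at 10.05, 11.11 and 10.65, and the cyclase CPS2 at 8.92, 9.96 and 9.53. Other members, outside the rule for named genes, differed. CPS4, KSL4, KSL7 and KSL10 were below background, with means of 4.59, 3.69, 4.35 and 4.13. CYP76M8, above background, was lowest in replicate 2 (7.99 against 8.07 in both others). The list shift therefore does not show a rise of phytoalexin synthesis. Chitinases were lower in replicate 1 in 9 of 14 genes (median -0.06, 0.57th percentile). Cht4 was at 4.58 against 6.48 and 5.76, below background in replicates 1 and 3. Cht2 was at 7.91 against 9.51 and 8.57, although the 3 probe sets of Cht2 disagreed in which array was highest. Defence and immune signalling was also lower in replicate 1 (median -0.08, 0.09th percentile), with 10 genes lower and 3 higher. The WRKY median there was -0.09 (1.04th percentile), but 3 genes were lower and 3 higher. Over alternatives that kept each call the replicate 1 medians ran from -0.23 to -0.03 for defence, -0.30 to -0.09 for WRKY factors, -0.23 to -0.06 for chitinases and -0.63 to -0.11 for diterpenoid genes, whose replicate 2 median ran from 0.12 to 0.53. Without replicate 2 the WRKY median in replicate 1 turned to 0.16 (75.82th percentile), and as a mean of probe sets it was -0.04 (3.50th), which also ended the call. Without replicate 2 or 3 the chitinase call ended (medians -0.02 and 0.00). The poly-A spike controls, which are added before labelling, were higher in replicate 2 than in replicate 1 in 35 of 36 probe sets, by a median of 0.25, and lower in replicate 3 than the mean of the others in 35 of 36, by a median of -0.19. Their 5' minus 3' contrast was lower in replicate 2 than in replicate 1 in all 12 probe-set pairs, which belong to only 4 spike transcripts, by a median of -0.11.

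The flowering-time, drought and heat shock lists were higher in replicate 2 as well. Flowering genes were higher in 10 of 12 (median 0.18, 99.98th percentile), with Hd3a at 11.48 against 11.07 and 11.10 and MADS14 at 12.24 against 11.78 and 11.87. MADS50, a flowering promoter, was at 8.94 in replicate 1 against 8.54 and 8.42. Drought and ABA genes were higher in 11 of 16 (median 0.11, 98.54th percentile). Heat shock genes were higher in replicate 2 in 39 of 52 (median 0.08, 98.35th percentile) and lower in replicate 3 in 39 of 52 (median -0.15, 0.46th percentile). HSFB2B, a heat stress factor, was at 5.70 in replicate 3, below background, against 6.69 in both others. HSP22.3 was at 7.08 in replicate 3 against 7.97 and 7.69. Over alternatives that kept each call the replicate 2 medians ran from 0.12 to 0.32 for flowering-time, 0.08 to 0.22 for drought and 0.05 to 0.16 for heat shock genes, and the replicate 3 median of heat shock genes from -0.19 to -0.08. Without replicate 3 the drought and heat shock calls in replicate 2 ended (medians 0.00 and 0.00). Of all probe sets 47.7% were equal between replicates 1 and 2, so these medians do not show that the 2 replicates were alike. The drought call in replicate 2 also ended as a mean over members (0.08, 82.24th percentile). Without replicate 2 the heat shock call in replicate 3 ended (median -0.09).

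Ribosomal protein and cell wall genes separated the replicates in another way. Of the 23 ribosomal genes 22 were lower in replicate 1 than the mean of the others (median -0.14, below every matched list). All 23 were higher in replicate 3 than the mean of the others (median 0.08, 100th percentile). The low replicate 1 enters that mean: without replicate 1 the median was 0.02, still outside. RPL30, outside the rule for named genes, was higher in replicate 2 than in replicate 3 (12.19 against 12.13). RPL18 was at 12.08, 12.24 and 12.39 in replicates 1, 2 and 3. RPS4 was at 12.33, 12.54 and 12.62, although the probe sets of RPS4 disagreed in which array was highest. RPL18 and RPL27, the latter outside the rule for named genes, also carry the names CL18 and CL27. Whether these members belong to the cytosolic ribosome was not checked. Cell wall growth genes were higher in replicate 3 in 38 of 58 (median 0.11, above every matched list) and lower in replicates 1 and 2 (medians -0.07 and -0.06), calls that ended without replicate 3. EXPB3 (LOC4349349) was at 11.09 in replicate 3 against 9.38 and 9.37, and EXPA2 (LOC4327568) at 8.74 against 6.96 and 7.69. CSLE1, a cellulose synthase-like gene of the same list, was at 10.46 in replicate 1 against 9.86 and 10.16. Over alternatives that kept each call the ribosomal median in replicate 3 ran from 0.02 (without replicate 1) to 0.15 (without replicate 2). The cell wall medians ran from -0.14 to -0.07, -0.11 to -0.04 and 0.08 to 0.25 in replicates 1, 2 and 3. Beside these shifts, the 5' minus 3' contrast of the poly-A spikes was lower on array 3 in 10 of 12 probe-set pairs, by a median of -0.27. The pairs belong to 4 spike transcripts, of which 3 had a lower median there and thr a higher one (0.06).

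Small shifts completed the set. In replicate 1 chlorophyll synthesis was lower (median -0.05), dehydrins and LEA proteins were lower (-0.11) and sugar and starch genes were higher (0.04). The dehydrin call ended without replicate 2 (-0.10), without replicate 3 (0.00) and without probe sets whose suffix marks shared probes (-0.06). The sugar call ended without replicate 2 (0.04), without replicate 3 (0.00), as a mean of probe sets (0.03) and as a mean over members (0.05). In replicate 2 nitrogen assimilation was lower (-0.03), yet its ammonium transporter AMT1-2 was at 8.13 against 7.16 and 7.29. The nitrogen call ended with quantile normalization again (-0.03) and without replicate 3 (0.00), and as a mean over members the value was 0.06. In replicate 3 chlorophyll synthesis (0.02) and diterpenoid genes (0.04) lay above matched lists, but without replicate 1 they were at -0.00030 (92.94th percentile) and -0.12 (2.29th percentile). The diterpenoid call in replicate 3 also ended with quantile normalization again (0.06), as a mean of probe sets (0.04) and as a mean over members (0.03). Over alternatives that kept each call the chlorophyll medians ran from -0.07 to -0.03 in replicate 1 and 0.01 to 0.08 in replicate 3, dehydrins from -0.20 to -0.11, sugar and starch from 0.04 to 0.08, nitrogen from -0.06 to -0.03 and diterpenoid genes in replicate 3 from 0.04 to 0.12. Altogether 22 of 81 shifts lay outside the central 95% of matched lists, 9 in replicate 1, 8 in replicate 2 and 5 in replicate 3. Chance would put 4.05 outside if genes varied independently. Genes of a list can vary together, which random lists do not reproduce, so the excess over 4.05 is not a test. Lists of light harvesting, photosystems, the Calvin cycle, the clock, jasmonate, senescence, histones, cyclins, wax, seed storage, anther, root, meristem and reference genes had no shift outside that range. Percentiles describe these 3 arrays, since each replicate is 1 sample and the shifts of 3 arrays are not independent of one another.

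**Figure D2:**
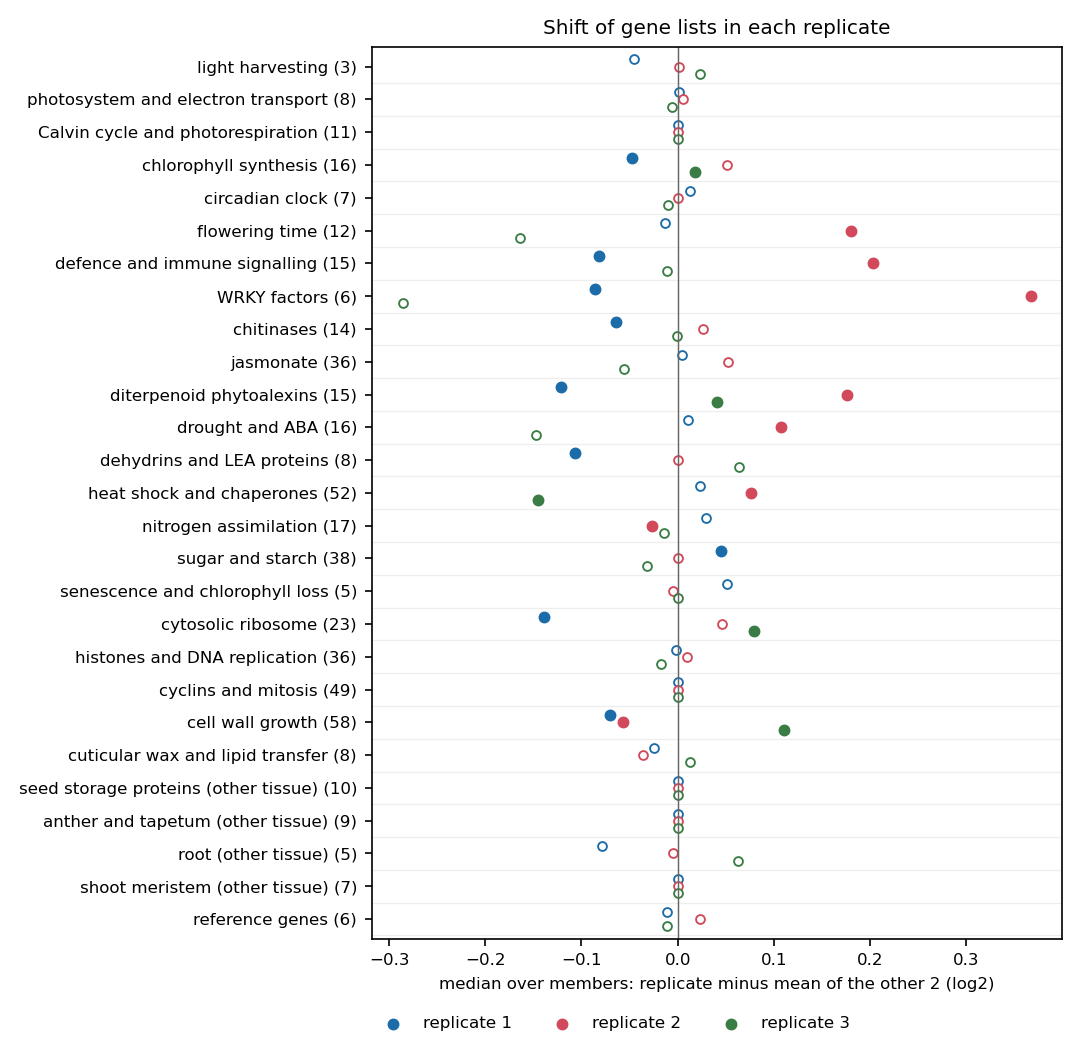
Median over list members of each replicate's signal minus the mean of the other replicates (log2, horizontal axis) for the 27 gene lists, with the list size in brackets. Filled points lie outside the central 95% of 10000 random lists matched on signal and open points lie inside. WRKY factors reach 0.37 in replicate 2, and ribosomal genes lie at -0.14 in replicate 1.

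**Figure D3:**
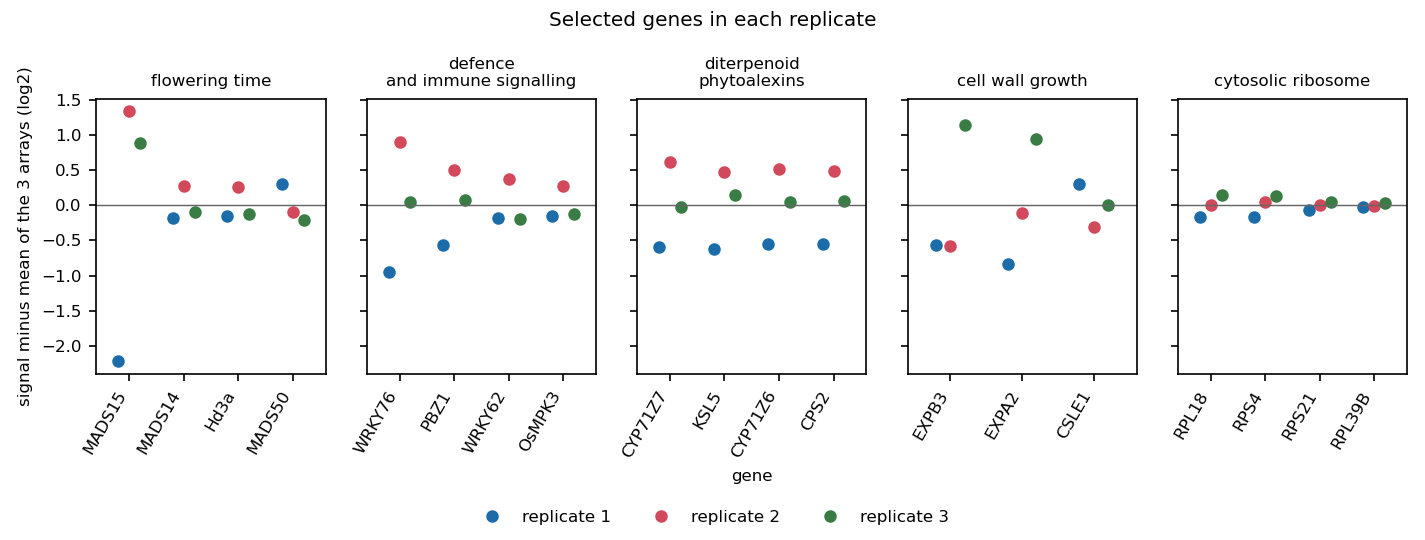
Signal of selected genes in each replicate, as the difference from the gene's mean over the 3 arrays (log2, vertical axis). Each point is 1 array, so no error is drawn. MADS15 is low in replicate 1 (5.57 against 9.12 and 8.67), the defence and diterpenoid genes shown are highest in replicate 2, and EXPB3 and EXPA2 are highest in replicate 3.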

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

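No paired analysis was possible because the labels give 1 group. Averaging replicates 1 and 2, dropping probe sets equal on all arrays and keeping only members fixed in advance, in the lists first written by locus, were alternatives chosen after seeing the data. The count of probe sets with excess spread was 0 with limma under every setting tried, with unadjusted counts under 0.05 from 0 (eBayes not robust) to 13895 (without replicate 3), and in simulated median-polished values it called 0 of the probe sets with added spread under each of these settings, though with other prior degrees of freedom than the data had (0.28 against 0.40 in the main fit). The mean count of probe sets at least 2-fold apart per pair, 266.7, was 158.3 among probe sets above the median signal, because fewer were counted, and 1638 at a 1.5-fold threshold; the range over leaving out each replicate was 182 to 325. The mean SD over pairs, 0.22, ranged from 0.15 to 0.25 over those. Lists outside for spread, 5, were 9 above the median signal, the cause was not tested, and 3 to 11 with each replicate left out. Shifts outside, 22 of 81, were 12 to 18 with each replicate left out and 10 with replicates 1 and 2 averaged, where fewer values exist; other settings gave counts within 1.5 times, 22 among them with only fixed members in the lists first written by locus and all other lists unchanged. The 8 lists of high signal stayed within 1.5 times in count. Of the single shifts, 173 values under alternatives kept their call, 21 lost it and 4 changed sign; of the spreads 41 kept it and 9 lost it. Of the 214 values that kept a call, 48 moved by over 1.5 times. Of the gene signals under alternatives, 534 stayed within the SD over arrays and 25 moved past it. Of these, 18 came from averaging the probe sets of a gene, and 7 from quantile normalization again, by at most 0.01. Averaging probe sets moved 15 of the 63 genes recomputed by at least 1.5-fold, the largest change being -4.38 (LIP9); the cause was not tested. The sign changes were nitrogen assimilation in replicate 2 as a mean over members (0.061) and 3 shifts with a replicate left out: diterpenoid genes in replicate 3 (-0.12 without replicate 1 to 0.12 without replicate 2), chlorophyll synthesis in replicate 3 (-0.00030 without replicate 1 to 0.045 without replicate 2) and WRKY factors in replicate 1 (0.16 without replicate 2, -0.30 without replicate 3); the cause was not tested. Signal over background limits dim genes: 47.1% of probe sets lay above the reporter bound on every array.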

Other observations

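The tests in this part were chosen only after the results had been seen, except that quantile normalization again was a planned setting, and the genes of this paragraph were picked by their values. Replicate 3 held 36 genes at least 2-fold above both other replicates, against 7 in replicate 1 and 10 in replicate 2. Genes at least 2-fold below both others numbered 5 in replicate 3, 10 in replicate 1 and 8 in replicate 2, and all these counts were made without a background filter. The laccase gene LAC7 was at 10.46 in replicate 3 against 7.21 and 7.65, the largest SD after MADS15 among genes with a published name. Pi21, a proline-rich gene whose loss gives blast resistance, was at 11.49 in replicate 3 against 10.27 and 10.02, read from a probe set shared between transcripts. ACO1, the last enzyme of ethylene synthesis, was at 7.86, 9.16 and 9.90 in replicates 1, 2 and 3, and CHS, chalcone synthase of the flavonoid pathway, at 8.86, 9.57 and 10.12. NAS3, a nicotianamine synthase of iron transport, was at 9.11 in replicate 3 against 10.59 and 10.11. The tubulin gene TUB6 was at 11.48 in replicate 2 against 10.10 and 10.03. The sugar transporter OsSWEET15 was at 5.33 in replicate 2, below background, against 6.35 and 6.69. BURP17 and the cytokinin enzyme LOGL3 were highest in replicate 1, at 11.22 and 10.42, against at most 10.03 and 9.43 elsewhere.

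Control probe sets also differed between arrays. The 5 rice rRNA probe sets had medians of 8.93, 8.48 and 8.61 in replicates 1, 2 and 3. All 5 were lower in replicate 2 than in replicate 1, by a median of -0.45, and all 5 were lower in replicate 3 than the mean of the others, so replicate 1 was highest in each; there the ribosomal protein, defence and diterpenoid lists were lower (-0.14, -0.08 and -0.12). Of the 64 reporter sequences, 31 were higher and 9 lower on array 3 than the mean of the others. The 5' minus 3' contrast of the tag sequences, whose medians were 4.03, 4.03 and 4.31, was lower on array 3 in 4 of 4, by a median of -0.20.

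MADS15 was low in replicate 1 alone. A fault of 1 probe set is argued against, since 3 of its 4 probe sets were at least 2-fold lower there than in both other replicates, although the probe sets can share probes. Plants of replicate 1 may have been less advanced towards flowering, a hypothesis under which Hd3a, MADS14, MADS18 and MADS34 would all be lowest there. Of these 4 genes 3 were lowest in replicate 1, and MADS18 was lowest in replicate 3 (12.20, 12.31 and 12.01). A random choice of array for each gene, taken as independent, gives as many with a chance of 0.111, and Hd3a differed from replicate 3 by little (11.07 against 11.10). The flowering promoter MADS50, not among these 4, was highest in replicate 1 (8.94 against 8.54 and 8.42). MADS34, outside the rule for named genes, was at 4.56, 6.17 and 5.18 in replicates 1, 2 and 3, below background in replicates 1 and 3, and without it the count is 2 of 3. That hypothesis stays open, and no biological difference between the replicates is named in the design.

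Defence, WRKY and diterpenoid lists were higher in replicate 2. A signal-dependent difference left by the normalization would be shared by the random lists, which were matched on signal. Their median shifts in replicate 2 were 0.04, 0.06 and 0. Quantile normalization again left 3 of the 3 lists above the 97.5th percentile, with medians of 0.14, 0.32 and 0.19. It could not decide the question, because the matching was already in place and the lists were picked by the same percentile. Blast fungus RNA remains open: 0 of the 10 Magnaporthe control probe sets were highest on array 2, but their medians of 5.52, 5.43 and 5.60 lie at background, where a small amount could not be seen. Wounding at harvest also remains open, as the jasmonate list lay at the 92.49th percentile in replicate 2, above most matched lists and short of the bound.

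Replicate 3 lay farther from replicates 1 and 2 than these lay from each other. A signal-dependent difference is argued against as the whole cause: after removing the median difference within 20 bins of signal, the SDs of its pairs were still at least 1.56 times that of replicates 1 and 2. Shorter labelled copies on array 3 may contribute, since the 5' minus 3' contrast of the poly-A spikes was lower by a median of -0.27 there, in 3 of 4 spike transcripts, against 0.01 for hybridization spikes, which are added after labelling. The 7 probe-set pairs of 5 rice housekeeping transcripts were lower in 6 of 7, with a median change of -0.011 and a range from -0.45 to 0.08, which leaves it open. A difference between the plants cannot be told apart from it with these arrays, and no biological explanation was tested.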
